A study of Mus musculus with 8 samples.

How the data were processed

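Islets of 8 mice were profiled as 8 libraries, 4 labelled WT (floxed Ern1) and 4 labelled KO (beta cell knockout). Per the labels' protocols, the mice were 7 weeks old and received tamoxifen, prepared at 10 mg/ml, by intraperitoneal injection on 5 consecutive days. Islets were freed with collagenase and protease, parted from exocrine tissue on a density medium and picked by hand, and RNA was extracted on silica columns. The series' design text gives 4 mice per genotype, so the libraries were taken as separate animals.

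Per the submitters' processing notes, the tools were bcl2fastq 2.20, STAR 2.5.3a, RSEM 1.2.31 and edgeR 3.16.15, with genome build GRCm38.p5; their settings and the strandedness of the library kit are not given in the sources used here. The table deposited by the authors held 14126 genes. Its 8 per-library columns were normalized counts that the authors rounded to whole numbers, a score in no fixed unit rather than raw counts. This reading rests on the column names and on the values: factors from the median of ratios lay between 0.994 and 1.01 over the 8 libraries, although the totals differed. The same table, deposited by the authors, gave their log2 fold change and log2 CPM, the likelihood ratio as a score, a p-value and an adjusted p-value per gene. The smallest p-value and its FDR imply adjustment over 14613 genes, more than the table holds, so genes had been filtered. Their calls were 2285 genes higher and 1852 lower in KO at an FDR under 0.05. A gene that every library lacks, or nearly so, is therefore not analysed here, which reaches the immune cell lists most: 638 of 711 list entries were measured.

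The design chosen before the data were examined assumed counts and a quasi-likelihood test of them. The values were another unit, so the fallback written with that design was used: limma-trend with empirical Bayes moderation (limma 3.58.1 in R 4.3.3) on log2(value + 1), on genes with a value of at least 1 in at least 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. It kept 14121 genes. Fold changes are on this log2(value + 1) scale, which understates those of low genes. The standard errors are limma's moderated ones. No count test was run, since the values are not counts. The median log2 fold change over tested genes was -0.0008.

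Sequencing depth per library was sought in the spacing of the low values, which are multiples of 1 factor if whole reads were scaled. A factor stood out for WT replicate 4 alone (1.123, correlation of the predicted and observed spacing of 0.872), and gave 31040947 reads. The other 7 libraries gave no clear factor (best correlation from 0.399 to 0.763), so their depth is unknown and no counting interval is given. Precision therefore rests on the spread between 4 libraries per group. On simulated data with these gene means, for KO against WT with 4 libraries each and 14126 genes, 56% of genes changed 2-fold and 88% of those changed 4-fold were called. The changed genes were drawn only from genes above a minimum mean value, so these shares do not cover lower ones. Of all calls 1.37% were genes that had not been changed, and none of 30 unchanged random lists was called. Each gene was drawn independently, so the simulation holds no correlation between genes. It therefore does not show how often lists of correlated genes, or genes that shift together between libraries, are called by chance.

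Genes were named by a rule fixed before the data were examined: Ern1 and Xbp1; the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 1 and no overlap between groups, leaving out predicted, RIKEN and pseudogene models; up to 4 called members per list with the largest change, or the 2 most abundant if none was called; 16 fixed genes; and the gene with the smallest p in each direction. This gave 106 genes, of which some are not reported here. Npy, Wars, Dapp1, Dpp4 and G6pc2 fall outside it and were named after their values were seen, to complete counts. Xist and Rn7sk fall outside the rule too. Older symbols in the table (Ero1lb for Ero1b) were matched through RefSeq synonyms whose positions overlap. Coordinates are from GENCODE M21, whose GRCm38 chromosomes match those of GRCm38.p5, and 14114 gene IDs were found in its name table.

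The 28 gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry, whose p tests whether a list's genes move one way on balance and does not compare the list with other genes. After seeing the data, an exact permutation test of each list's mean log2 level per library was added.

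The replicate numbers 1 to 4 occur in both groups. Deviations from the group means of same-numbered libraries correlated, across genes with a mean value above 50, with r of 0.329, 0.585, 0.666 and 0.383. These are across genes, which are not independent replicates. Each was above 0.1, so the numbers were treated as pairing the samples, as a reading of the data, since the labels do not say what a number marks. The correlation of WT replicate 1 with KO replicate 2 was 0.456, so the pairing reflects the 2 sets of libraries (1 and 2, 3 and 4) at least as much as single numbers. A fit with the replicate block called 1999 genes higher and 1649 lower, and its values stand beside a result where they changed its call.

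Alternatives planned before the data were examined were median-of-ratios scaling, equal totals, totals without Ins1, Ins2, Gcg, Sst, Ppy, Pyy, Iapp and mitochondrially encoded genes, removal of acinar markers before scaling, limma-voom with the values taken as if counts, no filter, a CPM filter, pseudocounts of 0.1 and 0.25, stricter thresholds, the replicate block and leaving out each library. Added after seeing the data were a term for libraries 1 and 2 against 3 and 4, each of these sets alone, the mean acinar level as a covariate, fry with the replicate block and the authors' deposited likelihood ratio test.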

Results

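Bulk RNA sequencing was used to profile pancreatic islets, the clusters of hormone-secreting endocrine cells of the pancreas. They came from 7-week-old NOD/ShiLtJ mice, a strain that develops autoimmune diabetes. The question was how islet transcription at this age differed with loss of Ern1 from the insulin-secreting beta cells, as described by the labels. Ern1 encodes the endoplasmic reticulum (ER) stress sensor IRE1α. The 2 groups were 4 libraries labelled WT, from mice carrying floxed Ern1, and 4 libraries labelled KO, from mice described as lacking IRE1α in beta cells. Tamoxifen, a ligand of the oestrogen receptor that is used to switch on inducible recombinases, is recorded for both groups, and the labels name no recombinase. The deposited table held normalized values for 14126 genes, rounded to whole numbers. They summed to between 32024139 in KO replicate 4 and 34858983 in WT replicate 4. These totals follow normalization and are not sequencing depths. Mitochondrial ribosomal RNA took 13.2% to 20.3% of them, and Rn7sk, a non-coding RNA gene, 0.53% to 1.74%. Sequencing depth was unknown for 7 libraries, and for WT replicate 4 the spacing of low values corresponded to 31040947 reads, if whole reads had been scaled.

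The libraries separated by genotype label and also by replicate number. On a principal component plot PC1 held 45.1% and PC2 33.1% of the variance, and libraries 1 and 2 of each label lay apart from libraries 3 and 4. With genotype in the model, 1325 genes were higher and 856 lower in libraries 3 and 4 (limma-trend, adjusted p under 0.05). Fos, an immediate early transcription factor gene that responds within minutes to stimulation or handling, had a mean value of 5274 in libraries 1 and 2 and 62222 in libraries 3 and 4. Of the 24 dissociation and immediate early genes, 20 were higher in libraries 3 and 4, with a median log2 difference of 3.37 (adjusted p = 5.46e-23 by camera, 0.191 with an estimated correlation). Higher there too were 13 of 17 chemokine, 14 of 22 macrophage, 16 of 30 interferon-stimulated, 16 of 22 stellate and 7 of 10 Schwann cell genes, with median log2 differences of 3.35, 0.78, 0.63, 1.22 and 1.72. Of 26 acinar genes 2 were higher, with a median of 1.39. The camera tests of these 6 lists were called, the highest adjusted p being 1.63e-06 for the acinar list, and none was called with an estimated correlation (lowest adjusted p = 0.127, for macrophage and Schwann cell genes). Rn7sk had a log2 difference of 0.94 between these sets, which did not pass (adjusted p = 0.0617, limma-trend). Nothing in the labels records a batch.

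**Figure D1:**
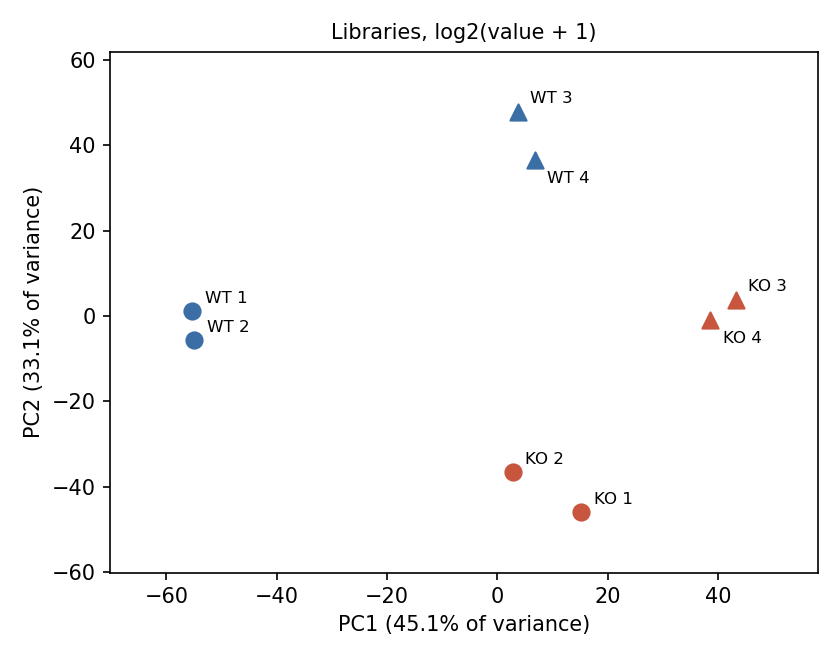
Each point is 1 library placed on the first and second principal components of log2(value + 1), with the share of variance on each axis. Blue marks libraries labelled WT, red those labelled KO, circles libraries 1 and 2 and triangles libraries 3 and 4, and both the labels and the replicate numbers separate the libraries.

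The targeted gene, Ern1 (ENSMUSG00000020715, GRCm38 chromosome 11, 106394650 to 106487852, minus strand, protein coding), was higher in the libraries labelled KO. Its values were 7223, 7390, 6922 and 7216 in KO replicates 1 to 4 and 5549, 5164, 4622 and 4500 in WT replicates 1 to 4. The means were 7187.8 ± 194.6 and 4958.8 ± 488.0 (SD, n = 4 each), a log2 fold change of 0.54 ± 0.08 (SE, adjusted p = 0.00234, limma-trend). The value adds reads over the whole gene. The sources used here do not give the floxed exons, and a total over all exons can hold reads from outside them, so this total does not check the labels. The total was not lower in libraries labelled KO, which leaves a loss of the floxed exons untested, and all directions below rest on the labels alone. Xbp1, whose messenger RNA is spliced by IRE1α, had values of 9022.2 ± 1834.5 in libraries labelled KO and 10995.5 ± 977.7 in those labelled WT (log2 fold change of -0.30 ± 0.14, adjusted p = 0.168). That difference did not pass the threshold, but did with libraries 1 and 2 against 3 and 4 as a term (adjusted p = 0.0333), and not with the replicate block (0.080). Its splicing was not analysed here.

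Across the 14121 genes tested, 1562 were higher and 1385 lower in libraries labelled KO than in those labelled WT (limma-trend, adjusted p under 0.05). Among the called genes with the largest rises under the naming rule was Esr1, encoding oestrogen receptor alpha, on chromosome 10 (4611593 to 5005614). It went from 21.8 ± 7.8 to 6331.5 ± 2085.8 (log2 fold change of 8.13 ± 0.30, adjusted p = 3.44e-06). Areg, which encodes the growth factor amphiregulin, went from 3.0 ± 2.6 to 674.5 ± 248.2 (7.63 ± 0.59 on the log2 scale, adjusted p = 1.12e-04). Prrxl1, a homeobox gene listed at 0, 0, 1 and 0 in WT libraries, lay between 108 and 256 in libraries labelled KO. Its log2 fold change of 7.04 is set by the pseudocount, being 9.74 with a pseudocount of 0.1 and 8.74 in the authors' deposited table, and that of Areg was 8.71 with a pseudocount of 0.1, so these 3 genes are not ranked. Others among the 10 largest rises were Slc5a10, a sugar transporter gene, Csn3, a milk casein gene, Aass, an enzyme of lysine breakdown, Wdr72, Rasd2 and Ccdc3, with log2 fold changes from 4.86 to 4.16. Ccdc3, with WT values of 3, 7, 0 and 7, went from 4.16 to 3.49 without WT replicate 3 and to 5.15 with a pseudocount of 0.1. The smallest p among rises was that of Aass, with 62.0 ± 5.0 in WT and 1294 ± 171 in libraries labelled KO (adjusted p = 7.35e-07).

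The 10 largest falls were in Cdh7, encoding a cadherin, Cib3, Snora78, T2, Sptbn5, Mlph, Defb1, encoding a defensin, Trpm5, St8sia1 and Cyp4f39. Cdh7 (chromosome 1, 109982431 to 110140157) fell from 314.8 ± 42.3 to 29.3 ± 7.9 (log2 fold change of -3.41 ± 0.22, adjusted p = 7.12e-05). Trpm5, a cation channel of beta cells (chromosome 7, 143069153 to 143094642), fell from 5539 ± 888 to 829.8 ± 188.0 (-2.76 ± 0.19, adjusted p = 7.77e-05). The smallest p among falls was that of St8sia1, with 636.8 ± 78.3 in WT and 94.8 ± 12.6 in libraries labelled KO (adjusted p = 3.05e-05). Snora78, a small nucleolar RNA gene, rested on an uneven WT group with values of 47, 67, 416 and 24. Its log2 fold change was -3.21, -2.39 without WT replicate 3 and -3.88 in the authors' deposited table, and its call ended without KO replicate 3 or 4 (highest adjusted p = 0.0531).

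The contrast was also fitted within each set of replicate numbers. Libraries 1 and 2 alone called 1740 genes higher and 1540 lower, and libraries 3 and 4 alone 1600 and 1604. Of the 2947 genes called with 8 libraries 1466 were called in both sets. The difference between labels itself differed between the sets for 14 genes (interaction term, limma-trend, adjusted p under 0.05), and for 2652 at an unadjusted p under 0.05, where chance gives about 706. Differences of list results between the sets were not tested. With the set of libraries as a term the counts were 2400 and 2102. Without WT replicate 2 the count of lower genes was 863 and without KO replicate 4 it was 909. The split of calls was 53% higher as deposited. It was 63.2% higher (1746 against 1017) with totals that left out 7 hormone genes and mitochondrially encoded genes.

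**Figure D2:**
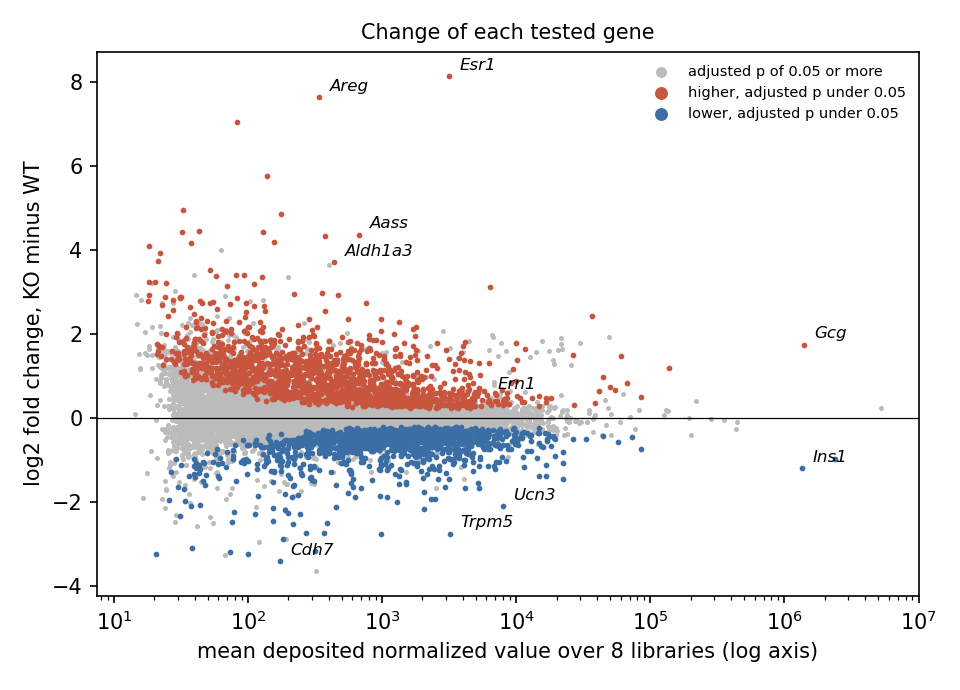
Each point is 1 of the 14121 tested genes, with its mean normalized value over the 8 libraries on a log axis and its log2 fold change, KO minus WT. Red points are the 1562 genes higher and blue points the 1385 genes lower in libraries labelled KO at an adjusted p under 0.05, and grey points did not pass.

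Among targets of the IRE1-XBP1 branch, which encode the machinery that moves new proteins into the ER and clears misfolded ones, more fell than rose. Of 50 members 29 fell, 2 rose and 19 did not pass. Adjusted over the list alone, 33 fell and 2 rose. Sec61a1, a subunit of the translocation channel, fell from 12224 ± 946 to 8205 ± 748 (log2 fold change of -0.58 ± 0.09, adjusted p = 0.00277). Wfs1, an ER membrane protein gene, fell by 0.95, Spcs3, of the signal peptidase, by 0.92 and Derl2, of ER-associated degradation, by 0.76 on the log2 scale. Kdelr3, encoding a receptor that returns proteins to the ER, rose from 248.0 ± 38.3 to 566.8 ± 67.5. Dnajb9, an XBP1 target encoding an ER co-chaperone, had a log2 fold change of -0.26 ± 0.27 (adjusted p = 0.537). The list's camera test gave an adjusted p = 1.10e-10, and an adjusted p = 0.569 with an estimated correlation. Values are those of whole islets. A lower share of beta cells, left open below, was therefore not told apart from a change within cells, for this list or those that follow.

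ER chaperone and oxidative folding genes went both ways. Of 32 members 11 fell and 4 rose, and 17 did not pass (adjusted over the list alone, 12 fell and 4 rose). Atf6b, a stress-activated transcription factor gene, fell by 0.78, and Ero1lb, a beta cell oxidoreductase gene, by 0.75 on the log2 scale. Hsp90b1, encoding the chaperone GRP94, rose from 48819 ± 6445 to 86150 ± 8410 (log2 fold change of 0.82 ± 0.13, adjusted p = 0.00249), and Derl3 rose by 0.93. Hspa5, encoding the main ER chaperone BiP, was at 69885 ± 4654 in WT and 99009 ± 16832 in libraries labelled KO (0.49 ± 0.13, adjusted p = 0.0323). Its call ended without WT replicate 2, 3 or 4, or without KO replicate 3 or 4 (highest adjusted p = 0.0890) and in the authors' deposited table (FDR 0.176). The list as a whole was called down with adjusted p = 0.0309 by camera and adjusted p = 0.818 with an estimated correlation. That call ended without WT replicate 1, WT replicate 2 or KO replicate 1 (highest adjusted p = 0.116), with the acinar level as a covariate (0.307) and in libraries 3 and 4 alone (0.573).

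Of 41 measured targets of the PERK-ATF4-CHOP branch, which adjusts amino acid supply under stress, 10 rose, 1 (Wars) fell and 30 did not pass (12 and 1 adjusted over the list alone, and 15 and 4 with the replicate block). Slc7a3, an amino acid transporter gene, rose from 17.0 ± 10.8 to 171.3 ± 62.8 (log2 fold change of 3.39 ± 0.45, adjusted p = 0.00134). Stc2, encoding stanniocalcin 2, rose by 1.98 ± 0.20, Slc7a11, encoding a cystine transporter, by 2.14 ± 0.46 and Trib3, a pseudokinase gene induced by CHOP, by 2.08 ± 0.43. Ddit3, encoding CHOP itself, had a log2 fold change of 0.98 ± 0.69 (adjusted p = 0.35), an adjusted p = 0.0229 with the replicate block and an FDR of 8.68e-07 in the authors' deposited table. Its values were 477 and 499 in WT libraries 1 and 2 and 3000 and 2644 in WT libraries 3 and 4. The list's adjusted p was 0.0250 (higher) by camera, 0.818 with an estimated correlation and 0.0757 by fry. The camera call ended without WT replicate 1 or 2 or KO replicate 3 or 4 (highest adjusted p = 0.132), and with the acinar level as a covariate (adjusted p = 0.438). In libraries 3 and 4, 12 members were higher than in libraries 1 and 2. Of 14 measured substrates of regulated IRE1-dependent decay, the cleavage of other messenger RNAs by IRE1α, 1 rose (Scara3, 1.92), 1 fell (Tapbp) and 12 did not pass. Adjusted over the list alone the counts were 1 and 1, and with the replicate block 3 and 1 (camera adjusted p = 0.719). The call of Tapbp ended without KO replicate 3 or 4 (highest adjusted p = 0.0636).

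Among genes of beta cell identity and maturity, more fell than rose. Of 39 measured members 20 fell, none rose and 19 did not pass, and adjusted over the list alone 23 fell and 4 rose. With the replicate block 20 fell and 1 rose. Ucn3, a maturity marker encoding urocortin 3, fell from 12883 ± 1263 to 3073 ± 738 (log2 fold change of -2.10 ± 0.18, adjusted p = 1.51e-04). Slc2a2, encoding the glucose transporter GLUT2, fell from 32748 ± 6675 to 11718 ± 1017 (-1.46 ± 0.15, adjusted p = 3.55e-04), and Glp1r, the receptor of the incretin GLP-1, fell by 1.66 ± 0.14. Ins1, an insulin gene, fell from 1877298 ± 100561 to 828271 ± 173400 (-1.20 ± 0.24, adjusted p = 0.00794). Ins2, the other insulin gene, was at 3141092 ± 145806 in WT and 1605798 ± 230749 in libraries labelled KO (-0.98 ± 0.27, adjusted p = 0.0309, and adjusted p = 0.104 with the replicate block). The Ins2 call also ended without WT replicate 1 or 2, or without KO replicate 1, 3 or 4 (highest adjusted p = 0.0951), with totals free of hormone genes (adjusted p = 0.0531) and in the authors' deposited table (FDR 0.118). Ins1 and Ins2 are near-identical in coding sequence, so the division of reads between them is uncertain. Both insulin genes together took from 14.2% to 15.8% of the total in WT libraries and from 6.2% to 8.9% in those labelled KO. Mafa, a maturity transcription factor gene, had a log2 fold change of -1.0 ± 0.42 (adjusted p = 0.124), of 0.02 in libraries 1 and 2 and of -2.02 in libraries 3 and 4, and its FDR was 0.0134 in the authors' deposited table. The list's adjusted p was 5.40e-08 by camera and 0.348 with an estimated correlation.

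Of 23 measured markers of endocrine progenitors and dedifferentiation 10 rose, 1 (Npy) fell and 12 did not pass (13 and 2 adjusted over the list alone, and 12 and 2 with the replicate block). Aldh1a3, a retinaldehyde dehydrogenase gene used as a marker of dedifferentiated beta cells, rose from 61.3 ± 12.4 to 814.5 ± 184.9 (log2 fold change of 3.70 ± 0.20, adjusted p = 3.38e-05). Cck, encoding cholecystokinin, rose from 1.0 ± 0.8 to 35.3 ± 21.1, with a log2 fold change of 4.10, and of 5.44 with a pseudocount of 0.1. Slc5a10 belonged to this list too. The list's adjusted p was 2.02e-04 by camera and 0.473 with an estimated correlation. Genes normally kept silent in beta cells, the disallowed genes, rose in 13 of 28 cases, with 1 (Dapp1) lower and 14 not passing (18 and 1 adjusted over the list alone). Acot7, a thioesterase gene, rose by 1.26 ± 0.24, and Igfbp4, which binds insulin-like growth factors, by 1.17 ± 0.17 on the log2 scale. The adjusted p was 5.17e-06 by camera and 0.547 with an estimated correlation. In libraries 3 and 4, 6 members were higher than in libraries 1 and 2 (camera adjusted p = 0.0028, and 0.578 with an estimated correlation).

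**Figure D3:**
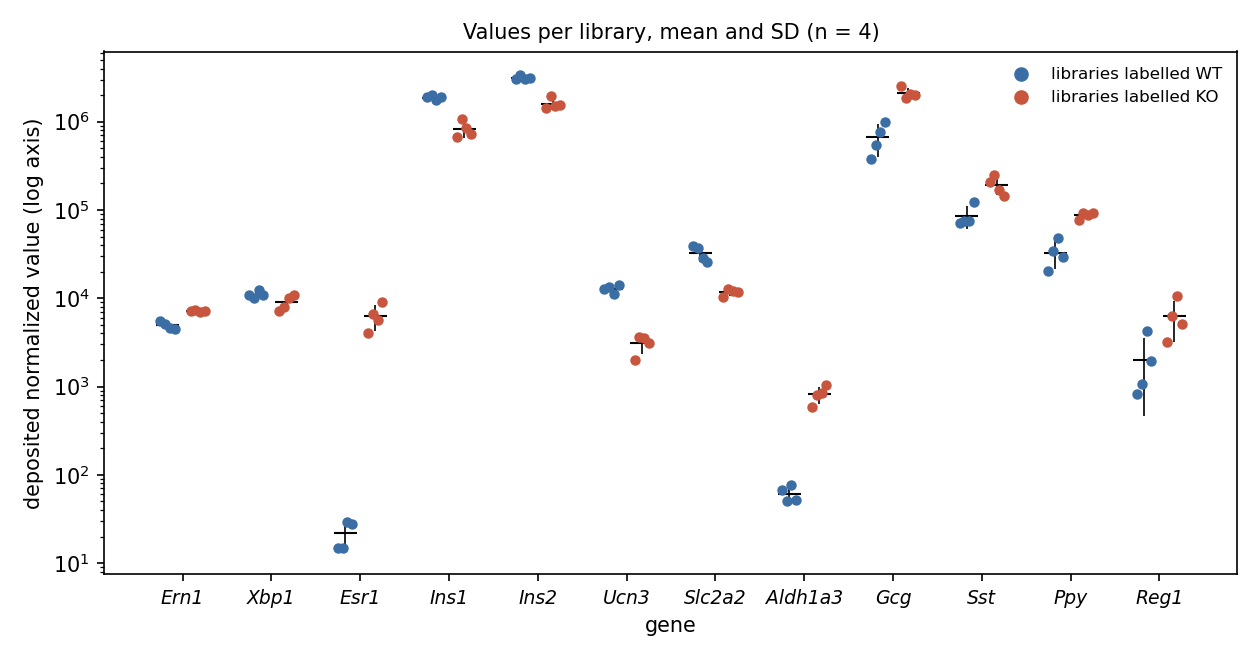
Deposited normalized values per library on a log axis for 12 genes, in blue for libraries labelled WT and red for those labelled KO, with horizontal bars at the means and vertical bars for SD (n = 4). All 4 libraries labelled KO lie below all those labelled WT for Ins1, Ins2, Ucn3 and Slc2a2, and above them for Ern1, Esr1, Aldh1a3, Gcg, Sst and Ppy.

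Among markers of the other islet endocrine cells, more rose than fell. Of 17 measured alpha cell markers 11 rose, 1 (Dpp4) fell and 5 did not pass (13 and 1 adjusted over the list alone). Gcg, the glucagon gene, rose from 671723 ± 273661 to 2115634 ± 292944 (log2 fold change of 1.74 ± 0.33, adjusted p = 0.00657), and Etv1, a transcription factor gene, by 1.71 ± 0.19. The rise of Gcg was 2.27 in libraries 1 and 2 and 1.21 in libraries 3 and 4. Of 10 measured delta, PP and epsilon cell markers 8 rose and 2 did not pass (8 adjusted over the list alone). Sst, encoding somatostatin, rose by 1.18 ± 0.23, Ppy, encoding pancreatic polypeptide, by 1.47 ± 0.23 and Pyy, encoding peptide YY, by 1.49 ± 0.16 on the log2 scale. Sst was not called in libraries 3 and 4 alone, where its log2 fold change was 0.71. The adjusted p was 2.89e-05 for the alpha list and 2.27e-05 for the delta, PP and epsilon list by camera, and 0.473 and 0.348 with an estimated correlation.

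Lists of acinar, ductal and stellate cell markers were called higher by camera with the preset correlation, with few single members passing, and none of these lists by fry (adjusted p = 0.212, 0.0974 and 0.105). Of 26 acinar markers, genes of the enzyme-secreting exocrine cells, 2 rose (Reg1 and Try5), 1 (Bhlha15) fell and 23 did not pass, and adjusted over the list alone none rose and 1 fell. With the replicate block 10 rose and 1 fell, and 23 were higher and 1 lower in the authors' deposited table at an FDR under 0.05. The median log2 fold change was 1.65, and the adjusted p was 1.17e-04 by camera and 0.761 with an estimated correlation. The acinar genes took 0.11% to 1.26% of the total in WT libraries and 0.66% to 1.94% in those labelled KO. Reg1, encoding a lithostathine, was at 2014 ± 1547 and 6297 ± 3116, and its call ended without WT replicate 1, 2 or 4, or without KO replicate 2, 3 or 4 (highest adjusted p = 0.0957). That of Try5, a trypsinogen gene with close copies, ended without WT replicate 1, 2 or 4, or without KO replicate 1, 2, 3 or 4 (highest adjusted p = 0.104). Of 16 measured ductal markers 5 rose and 11 did not pass (6 adjusted over the list alone). Spp1, encoding osteopontin, rose from 1237 ± 287 to 11448 ± 5656 (log2 fold change of 3.12 ± 0.31, adjusted p = 3.37e-04). KO replicate 1 stood above the other libraries labelled KO, with a mean log2 level of the ductal list of 10.78 against 9.63 to 9.93 and a Spp1 value of 19589 against 6547 to 10277. Without it the log2 fold change of Spp1 was 2.82 (adjusted p = 4.74e-04). Muc1, at 1008 in that library and 143 to 316 in the other 3, was called (adjusted p = 0.0370) but not with the replicate block (adjusted p = 0.0522), nor without WT replicate 1 or 2, or without KO replicate 2 or 3 (highest adjusted p = 0.090). The ductal list's adjusted p was 0.0141 by camera and 0.756 with an estimated correlation, and 0.0561 without WT replicate 1. It was 0.0969 with the acinar level as a covariate and 0.310 in libraries 3 and 4 alone. Of 22 stellate cell and fibroblast markers, all with a positive log2 fold change, 2 rose (Lum and Mgp) and 20 did not pass (1 adjusted over the list alone). Mgp, encoding matrix Gla protein, rose by 1.10 ± 0.18. With the replicate block 16 rose, and the adjusted p was 2.41e-04 by camera and 0.721 with an estimated correlation. The call of Lum ended without WT replicate 1, 2 or 3, or without KO replicate 1, 3 or 4 (highest adjusted p = 0.0899).

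Markers of endothelial, Schwann and neuronal cells were not called as lists. Of 19 endothelial markers 1 fell (Esm1, by 0.55 ± 0.12) and 18 did not pass (1 adjusted over the list alone, 2 higher and 2 lower with the replicate block, camera adjusted p = 0.503). None of 10 Schwann and neuronal markers passed, over all genes or adjusted over the list alone, and 2 were higher with the replicate block. That list's adjusted p was 0.258, and 0.0479 with the replicate block (higher, 0.60 with an estimated correlation). In libraries 3 and 4 alone it was 0.00816, and that of the endothelial list 0.0198 (higher). Mbp, the most abundant Schwann list member, had a log2 fold change of -0.18 and Tubb3 of -0.07. Mbp was called lower with libraries 1 and 2 against 3 and 4 as a term (adjusted p = 0.0460, limma-trend).

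Of 27 T and NK cell markers 3 were measured and none passed over all genes or adjusted over the list alone (adjusted p = 0.548). Lck, a T cell kinase gene, was at 67.5 ± 43.6 in WT and 100.3 ± 19.1 in libraries labelled KO, and Cd4 at 49.0 ± 35.3 and 39.0 ± 15.3. Of 8 measured B cell markers Cd79a, of the B cell receptor, fell from 217.3 ± 32.2 to 92.8 ± 31.2 (adjusted p = 0.00628), and 7 did not pass (1 fell adjusted over the list alone, camera adjusted p = 0.151). In libraries 3 and 4 alone the B cell list was called lower (adjusted p = 0.00816). Of 22 macrophage and dendritic cell markers 1 (Mrc1) was called higher, none adjusted over the list alone (camera adjusted p = 0.485). The Mrc1 call ended without WT replicate 1 or 3, or without KO replicate 3 or 4 (highest adjusted p = 0.0798). Of 17 measured chemokine and cytokine genes Cx3cl1, a chemokine gene, rose by 0.87 ± 0.20, Csf1 fell and 15 did not pass (1 and none adjusted over the list alone, 2 and 1 with the replicate block, camera adjusted p = 0.517). The call of Csf1, a macrophage growth factor gene, ended without WT replicate 2, 3 or 4, or without KO replicate 1, 2 or 4 (highest adjusted p = 0.0777), and with equal totals (adjusted p = 0.0506).

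Genes encoding type 1 diabetes autoantigens, the beta cell proteins that the immune system attacks in this disease, had 16 measured members, of which 5 fell and 11 did not pass (6 adjusted over the list alone). They were Gad1, Ins1, Ins2, Slc30a8 and G6pc2, and 4 of these 5 were also on the beta cell list. Gad1, encoding a glutamate decarboxylase, fell from 3149 ± 475 to 939.8 ± 212.3 (log2 fold change of -1.76 ± 0.18, adjusted p = 4.27e-04), and Slc30a8, encoding a zinc transporter of insulin granules, by 0.91 ± 0.13. The adjusted p was 0.0215 (lower) by camera and 0.473 with an estimated correlation. It was 0.0507 in libraries 1 and 2 alone and 0.0687 with the acinar level as a covariate. Of 22 measured genes of MHC class I antigen presentation 2 fell (H2-M3 and Tapbp) and 20 did not pass (2 adjusted over the list alone, and 5 with the replicate block). H2-K1, a classical class I gene of a family of close copies, had a log2 fold change of -0.45 ± 0.38 (adjusted p = 0.436, and 0.0405 with the replicate block but 0.0861 with libraries 1 and 2 against 3 and 4 as a term, and an FDR of 0.0187 in the authors' deposited table). B2m, encoding the class I light chain, had one of -0.18 ± 0.35. The MHC list's adjusted p was 0.132, and 0.0283 with the replicate block (lower, 0.644 with an estimated correlation). Of 30 measured interferon-stimulated genes 2 rose (Ifih1 and Ddx58), 1 (Oas2) fell and 27 did not pass (1 and 1 adjusted over the list alone, and 2 and 5 with the replicate block). Ifih1, encoding the RNA sensor MDA5, rose by 0.87 ± 0.11, Oas2 fell by 1.06 ± 0.24, and the Ddx58 call ended without WT replicate 1 or 2, or without KO replicate 1, 3 or 4 (highest adjusted p = 0.0887). The interferon list's adjusted p was 0.171, and 0.0219 with the replicate block (lower, 0.601 with an estimated correlation). The MHC and interferon lists were called lower in libraries 3 and 4 alone (adjusted p = 0.00266 and 0.00713), and with the acinar level as a covariate (9.61e-04 and 4.98e-05).

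**Figure D4:**
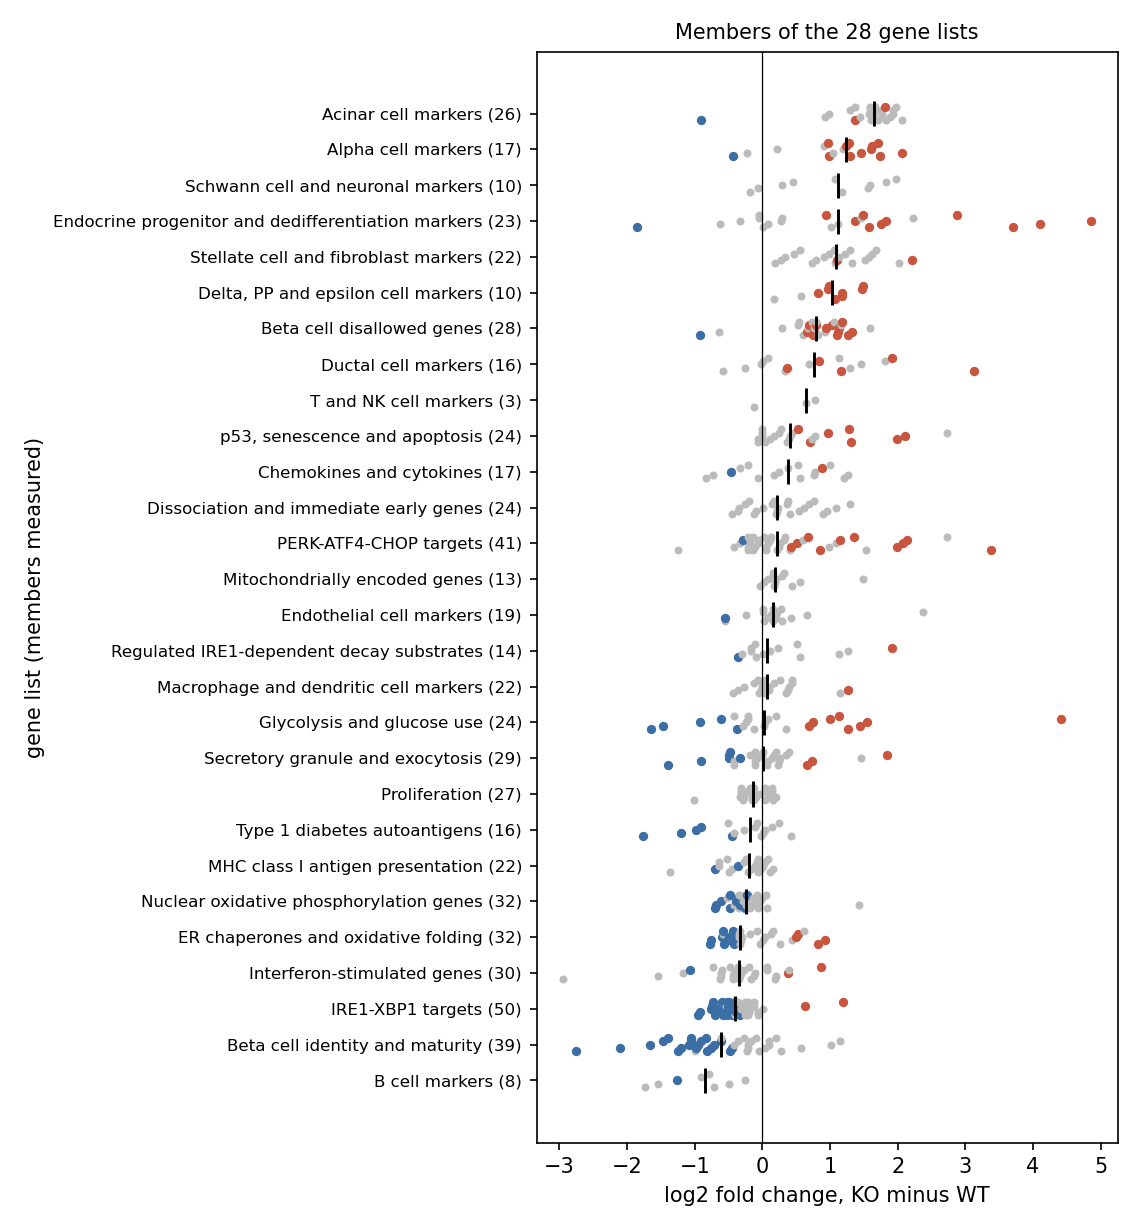
Each point is the log2 fold change, KO minus WT, of 1 member of a gene list, with the number of measured members in brackets and lists ordered by their median, a black bar. Red and blue points passed an adjusted p under 0.05 as higher and lower, and grey points did not, and the median was -0.61 for beta cell identity and 1.23 for alpha cell markers.

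Of 24 measured genes of p53 signalling, senescence and apoptosis 7 rose and 17 did not pass (9 adjusted over the list alone, and 14 with the replicate block). Eda2r, a p53-induced receptor gene, rose from 68.3 ± 15.6 to 292.8 ± 41.5 (log2 fold change of 2.10 ± 0.19, adjusted p = 2.30e-04), and Phlda3 by 1.28 ± 0.24. Cdkn1a, encoding the cell cycle inhibitor p21, was at 580.8 ± 415.0 and 1874 ± 468 (1.99 ± 0.51, adjusted p = 0.0236). Its call ended without WT replicate 2, or without KO replicate 1, 3 or 4 (highest adjusted p = 0.0649). That of Casp12 ended without WT replicate 1, 2 or 3, or without KO replicate 3 or 4 (highest adjusted p = 0.0833). The list's adjusted p was 0.00142 (higher) by camera, 0.673 with an estimated correlation and 0.0969 with the acinar level as a covariate. The list was also higher in libraries 3 and 4 than in libraries 1 and 2 (7 members, camera adjusted p = 2.06e-05, 0.191 with an estimated correlation), and Cdkn1a was at 207 and 252 in WT libraries 1 and 2 and at 1037 and 827 in WT libraries 3 and 4. None of 27 proliferation genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.485), and Mki67, a marker of dividing cells, was at 1520 ± 913 in WT and 1410 ± 355 in libraries labelled KO. The list was called lower in libraries 1 and 2 alone (adjusted p = 2.27e-06) and higher in libraries 3 and 4 alone (3.06e-04).

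Genes of glucose use went both ways, with 8 of 24 higher, 5 lower and 11 not passing (9 and 7 adjusted over the list alone, camera adjusted p = 0.677). Pcx, encoding pyruvate carboxylase, fell from 4477 ± 467 to 1442 ± 258 (log2 fold change of -1.64 ± 0.13, adjusted p = 1.13e-04), while Fbp2, encoding a fructose bisphosphatase, rose from 14.5 ± 1.3 to 45.3 ± 11.8. Of 32 nuclear genes of oxidative phosphorylation 10 fell and 22 did not pass (12 adjusted over the list alone, and 9 lower and 1 higher with the replicate block). Cox5a, a cytochrome c oxidase gene, fell from 583.3 ± 133.4 to 354.8 ± 13.3 (-0.69 ± 0.16, adjusted p = 0.0174), and its adjusted p was 0.0517 without WT replicate 2. The call of Ndufa2 ended without WT replicate 1, 2 or 3, or without KO replicate 3 or 4 (highest adjusted p = 0.0585), and that of Ndufb8 without WT replicate 1 or 2, or without KO replicate 1, 3 or 4 (highest adjusted p = 0.0573). That of Sdhc ended without WT replicate 1, 2 or 3, or without KO replicate 1, 2, 3 or 4 (highest adjusted p = 0.103). The list's adjusted p was 4.75e-05 (lower) by camera and 0.673 with an estimated correlation. None of 13 mitochondrially encoded genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.132, and 0.00145, higher, in libraries 1 and 2 alone), and mt-Co1 had a log2 fold change of -0.03 ± 0.16.

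Genes of secretory granules and exocytosis moved both ways, with 3 of 29 higher, 6 lower and 20 not passing (6 and 8 adjusted over the list alone, and 5 and 6 with the replicate block). Sytl4, a granule docking gene, fell by 1.4 ± 0.17 and Pam, encoding a peptide-amidating enzyme, rose by 0.73 ± 0.11 on the log2 scale. The call of Vgf ended without WT replicate 2, KO replicate 1 or KO replicate 3 (highest adjusted p = 0.0606). The camera test pointed down (adjusted p = 0.719), while the median and mean log2 fold changes were 0.01 and 0.04. None of the 24 dissociation and immediate early genes passed between labels, over all genes or adjusted over the list alone, and 1 was higher with the replicate block (camera adjusted p = 0.666), and Fos ranged from 2418 to 99042 in WT and from 6046 to 43120 in libraries labelled KO. That list was called higher in libraries 1 and 2 alone (adjusted p = 9.40e-06) and lower in libraries 3 and 4 alone (3.05e-04).

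In all, 14 of the 28 lists were called by camera with a preset correlation and none with an estimated correlation (lowest adjusted p = 0.348). By fry 8 lists were called, and 4 with the replicate block. The beta cell, delta-PP-epsilon and autoantigen lists were called in both (blocked adjusted p = 0.0246, 0.0268 and 0.0218). The block ended the fry calls of the IRE1-XBP1, progenitor, disallowed, alpha cell and p53 lists (adjusted p = 0.0968, 0.0575, 0.0575, 0.0727 and 0.0575) and added the Schwann list (0.0471). In an exact permutation test of each list's mean level per library, two-sided, the IRE1-XBP1, beta cell, progenitor, alpha cell, delta-PP-epsilon, autoantigen, ductal, glucose use and oxidative phosphorylation lists reached p = 0.0286. That is the smallest p that 4 against 4 libraries allow, and adjusted over the 28 lists it was 0.0889. Exons of several named genes overlap those of a neighbour in the annotation (Ddit3 with Mars, Tapbp with Zbtb22, Derl2 with Mis12, Kdelr3 with Ddx17, Trpm5 with Tssc4, Slc5a10 with Fam83g and Grap, Tgm2 with Rprd1b, Ndufa2 with Tmco6 and Sptbn5, Hsp90b1 and Pam with predicted genes). Their values are uncertain where the counting could not separate the pair.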

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

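The tests of beta cell share, acinar carry-over, acinar levels within pairs and the Esr1 ratio, the acinar covariate and the counts over splits for genes, by fry, with the replicate block and at an unadjusted p were chosen only after the result was seen, and the other tests were planned before their outcome was known.

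Single libraries stood far from the other 3 of their group in 16 of 212 sets of a named gene and a group, where chance gives about 10.6. In WT these were Prrxl1 (1 in replicate 3, 0 in the others), Wdr72 (28 in replicate 3 against 35 to 36), Snora78 (416 in replicate 3 against 24 to 67), Kdelr3 (191 in replicate 4 against 260 to 271), Glp1r (5353 in replicate 4 against 6623 to 6713), Crp (56 in replicate 4 against 20 to 24), Sst (122607 in replicate 4 against 70309 to 74438), Ins2 (3357417 in replicate 2 against 3044173 to 3096540) and Oas2 (46 in replicate 1 against 67 to 71). In libraries labelled KO they were St8sia1 (76 in replicate 2 against 99 to 102), Wfs1 (2568 in replicate 2 against 1954 to 1996), Ndufb8 (1880 in replicate 2 against 1502 to 1552), Ero1lb (45319 in replicate 1 against 68730 to 71629), Tgm2 (1385 in replicate 1 against 693 to 767), Nfib (1945 in replicate 1 against 884 to 1002) and Crp (389 in replicate 1 against 64 to 89).

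The number of called genes was set against other splits of the 8 libraries into 4 and 4. The genotype labels called 2947 genes and the highest other split, libraries 1 and 2 against 3 and 4, called 933, so that 1 of 35 splits reached the real count. That is the lowest share that 35 splits allow, and they ignore the pairing of replicate numbers, so it does not by itself exclude chance. Among the 8 splits that part every pair of replicate numbers, the others called 0 genes by limma at an adjusted p under 0.05. At an unadjusted p under 0.05 the labels gave 4942 genes and the highest other split 2733. For gene lists the outcome differed. The labels called 14 lists by camera with the preset correlation, and 15 of the 35 splits called as many, with 22 in the highest other split and 17 in the highest that parts every pair. Chance cannot be excluded for the number of lists called this way. By fry without a block the labels called 8 lists and the highest other split 7, so 1 of 35 splits reached that count. With the replicate block the labels called 3648 genes, 17 lists by camera and 4 by fry. The highest other of the 8 splits that part every pair gave 0 genes (limma; 5662 against 660 at an unadjusted p under 0.05), 17 lists by camera and 0 by fry. These 8 splits are too few for a share under 0.05.

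The called beta cell genes were lower, while most called markers of other islet endocrine cells were higher in libraries labelled KO. A lower share of beta cells would raise markers of every other cell type alike, and mean log2 fold changes were 1.53 for acinar, 1.10 for alpha, 1.09 for stellate, 0.99 for delta-PP-epsilon, 0.97 for Schwann, 0.83 for ductal, 0.43 for T and NK, 0.21 for endothelial, 0.17 for macrophage and -0.96 for B cell markers. The alpha minus endothelial level was higher by 0.886 with every library labelled KO above every WT library (exact permutation p = 0.0286, two-sided). That is the smallest p that 4 against 4 libraries allow, and the difference was 1.36 in libraries 1 and 2 and 0.41 in libraries 3 and 4. So alpha and endothelial markers did not rise alike, but stellate, delta-PP-epsilon, Schwann and ductal markers were close to alpha markers in mean change. The outcome therefore depends on the comparator, and a lower share of beta cells stays open as the whole cause or a part of it. Scaling set by a few abundant genes is argued against, since 38 of the 40 called members of the 3 lists kept call and sign with totals free of hormone and mitochondrially encoded genes. RNA from acinar cells is argued against only for the rise of called alpha and delta-PP-epsilon members as a set. With the acinar level as a covariate their median log2 fold change was 1.115, against 1.28 without it. Irx2, Crp, Sertm1 and Ins2 lost their calls in that fit (limma-trend, adjusted p from 0.0756 to 0.110), and the other called members named by the rule kept theirs. The fall of beta cell genes as a set was not weighed this way. The covariate also differed with the label (mean acinar level of 12.99 in KO and 11.46 in WT). A change of expression within islet cells that follows the genotype, and a larger share of alpha and delta cells in itself, stay open as hypotheses.

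The acinar genes had a median log2 fold change of 1.65, KO minus WT. Single calls were few (2 of 26 higher, 1 lower), and the list was not called by fry or by camera with an estimated correlation. Different amounts of acinar tissue carried over with the islets stay open as a cause. Within a genotype the acinar markers rose and fell together (median pairwise correlation of 0.970). Genotype means were removed for that value, so it does not bear on the difference between labels. The mean acinar level overlapped between labels (exact permutation p = 0.114 without pairing, two-sided), but it was higher in the library labelled KO in all 4 pairs of replicate numbers, by 0.60 to 3.64 on the log2 scale (sign-flip p = 0.125, the smallest that 4 pairs allow), and 10 members rose with the replicate block against 2 without it. That depends on matching libraries by single numbers, since WT replicate 3 (13.07) lay above KO replicate 4 (12.71) in the same set. Scaling is argued against as the cause, since the median was 1.70 with totals free of hormone and mitochondrially encoded genes. Bhlha15, an acinar marker that beta cells also express, fell, and a genotype effect on acinar cells was not tested.

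The Esr1 total was higher in every library labelled KO, and the lowest of them stood 140.7 times above the highest WT library. That ratio restates the rise and does not bear on its source, so reads from a Cre and oestrogen receptor fusion transgene and transcription of Esr1 itself cannot be told apart without values per exon, and the labels record tamoxifen but name no transgene. Oestrogen receptor activity in these islets stays open too. A list of oestrogen-responsive genes fixed before it was tested was higher as a set (camera p = 0.0169, with 5 of 16 measured members higher and none lower), but its p was 0.0608 with an estimated correlation. That camera setting called as many lists in many other splits of the libraries. Whatever the source of the Esr1 reads, their rise follows the same label as the described loss of Ern1. Differences between labels therefore cannot be assigned to loss of Ern1 alone.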

How the results depend on the processing

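The batch terms, the separate sets of libraries, the acinar covariate, the authors' test, fry with the replicate block and the permutation of list levels were chosen after seeing the data. The counts of 1562 higher and 1385 lower genes stayed within 1.5 times under every scaling, filter, pseudocount, limma-voom and replicate block setting. They were 2400 and 2102 with libraries 1 and 2 against 3 and 4 as a term, 720 and 587 at an FDR under 0.01, and 700 and 190 at an FDR under 0.05 with a change of at least 2-fold, where the last 2 settings call fewer by construction. Leaving out each library gave 1121 to 1684 higher and 863 to 1599 lower genes. Ern1 kept its direction and call in every limma fit (adjusted p from 4.46e-04 to 0.0149) and in the authors' deposited table. The 14 called lists were 0 with an estimated correlation, 8 by fry, 4 by fry with the replicate block and 0 by permutation of list levels, where the smallest p possible cannot pass after adjustment unless most lists reach it. Beyond the calls given with the results, the replicate block (Ins2, Muc1, Ddit3 and H2-K1 among named genes; 1999 and 1649 genes called) changed no other call of a named gene, or of a list by camera. Of 90 called named genes 68, and of 14 called lists 11, kept call and direction without any 1 library. The authors' deposited table called more members than the limma fit in most lists (higher and lower: PERK-ATF4-CHOP 17 and 3, IRE1-dependent decay 5 and 1, disallowed 20 and 1, MHC 0 and 7, interferon 2 and 9, B cell 0 and 3, chemokine 4 and 2, ductal 10 and 1, stellate 16 and 0, Schwann 4 and 0, p53 14 and 0, oxidative phosphorylation 1 and 15, immediate early 6 and 1), and Pcna was called lower there. The calls that ended with limma-voom were those of Snora78, Crp, Muc1 and Casp12 (adjusted p = 0.108, 0.0833, 0.0883 and 0.0595), and that of Sdhc ended with equal totals (adjusted p = 0.0570) and without hormone genes in the totals (0.0648). With the acinar covariate 26 named genes and 6 lists lost their call: ER chaperones, PERK-ATF4-CHOP, autoantigens, acinar, ductal and p53. Calls gained in the same direction were those of H2-K1 (log2 fold change of -1.23, adjusted p = 0.0163) and the MHC, interferon and B cell lists (9.61e-04, 4.98e-05 and 0.0369, lower). With libraries 1 and 2 against 3 and 4 as a term, Xbp1, Mbp, Pcna and Ddit3 gained a call and no named gene lost one. The MHC, interferon and Schwann lists were then called too (adjusted p = 0.0493, 0.0330 and 0.0493 by camera), and none with an estimated correlation. Libraries 1 and 2 alone gained Xbp1, Ddit3 and the proliferation, mitochondrially encoded and immediate early lists and lost the autoantigens (0.0507) and 10 named genes, Ins1 (0.0657), Cd79a (0.0669), Oas2, Derl3, Tapbp, Ins2, Ddx58, Mrc1, Csf1 and Hspa5. Libraries 3 and 4 alone gained Mki67, Pcna, Fos, Btg2, Mafa, Ddit3, B2m and the MHC, interferon, B cell, endothelial and Schwann lists and lost the ER chaperones (0.573), ductal markers (0.310) and 12 named genes, Crp, Sst, Sertm1, Ins2, Cx3cl1, Try5, Muc1, Esm1, Fbp2, Ndufa2, Cox5a and Sdhc.

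The following changed sign, and the cause was not tested. By fry with the replicate block the secretory granule list pointed up (adjusted p = 0.855). The log2 fold change of mt-Co1 was 0.0035 with equal totals, 0.010 without hormone genes in the totals, 0.038 in libraries 3 and 4 and 0.10 with the acinar covariate. In libraries 1 and 2 alone that of Cd4 was 0.17, Mki67 -0.74, Fos 0.97, Btg2 0.16, Mafa 0.024 and B2m 0.065, and the endothelial list's adjusted p was 0.608. In libraries 3 and 4 alone Tubb3 was at 0.059, and the adjusted p was 0.817 for macrophage, 3.06e-04 for proliferation, 0.698 for glucose use and 3.05e-04 for immediate early genes, where libraries 1 and 2 alone gave 2.27e-06 for proliferation and 9.40e-06 for immediate early genes. With the acinar covariate Ddit3 was at -0.26, and the adjusted p was 0.989 for IRE1-dependent decay, 0.702 for T and NK, 0.122 for macrophage, 0.142 for chemokine, 0.652 for Schwann, 0.0386 for proliferation and 0.00424 for immediate early genes.

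Leaving out single libraries also turned the sign of the following, none of which was called with all 8 libraries, and the cause was not tested. The log2 fold change ranged over mt-Co1 -0.14 to 0.040, Cd4 -0.55 to 0.30, Tubb3 -0.22 to 0.10, Mki67 -0.20 to 0.39, Fos -1.04 to 0.75, Btg2 -0.96 to 0.37, B2m -0.47 to 0.044. The adjusted p of the list test ranged over 0.121 to 0.985 for dissociation and immediate early genes, 0.0781 to 0.972 for macrophage and dendritic cell markers, 0.129 to 0.974 for chemokines and cytokines, 0.0295 to 0.737 for proliferation.

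Not run were the DESeq2 test and a likelihood ratio test of this work, which need counts. Depth is unknown for 7 libraries, so differences in it between libraries cannot be weighed.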

Other observations

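The chromosomal tests below were planned before their outcome was known, except that near Ern1, which was chosen after the result was seen, as was the grouping of genes by symbol.

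Genes were also grouped by the letters that open their symbol, for the 161 such families with at least 10 tested genes. Against 11.1% of all tested genes higher and 9.81% lower, 2 families passed an adjustment over 322 one-sided Fisher's exact tests, both for lower members. They were genes beginning with Atp, of ATP synthases and ATP-driven pumps, with 18 of 67 lower and 4 higher (adjusted p = 0.0106), and genes beginning with Sec, of protein transport, with 10 of 25 lower and 2 higher (adjusted p = 0.0106). The lower Sec genes include lower members of the IRE1-XBP1 list, such as Sec61a1, so this family is not independent of that list. Families with more rises than others did not pass: Pde, of phosphodiesterases, had 8 of 21 higher (adjusted p = 0.0765), Rgs, of G protein regulators, 7 of 17 (0.0765), and Scn, of sodium channels, 5 of 10 (0.0919). These directions held with each of the 4 other scalings, where 12 to 20 Atp and 9 to 10 Sec genes were lower and the family medians kept their sign. Genes are not independent, so these p-values describe the table.

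Xist, expressed from the inactive X chromosome of females, lay between 12097 and 32270 in all 8 libraries.

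Floxed alleles and transgenes bring along neighbouring DNA of the strain in which they were made, and such passenger variants may alter nearby genes. Within 10 Mb of Ern1 60 of 290 tested genes were called (20.7%), against 20.9% elsewhere (one-sided Fisher's exact test, p = 0.553), which does not exclude a few altered genes among them, so it stays open there. Within 10 Mb of Ins2 on chromosome 7 33 of 114 were called (28.9%), against 20.8% elsewhere (one-sided Fisher's exact test, p = 0.0250, and 0.0499 adjusted over both regions). Passenger variants around a transgene linked to Ins2 therefore stay open as a hypothesis, and the labels name no transgene. Trpm5, a called member of the beta cell list, lies within this region, so the count there is not independent of the fall of beta cell genes.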
